A study of Rattus norvegicus with 10 samples.

How the data were processed

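Messenger RNA was measured by bulk RNA sequencing in the junctional zone of the rat placenta, the endocrine and glycogen-storing trophoblast layer between the labyrinth and the decidua, dissected on gestation day 18.5 from Holtzman Sprague-Dawley rats. The labels give 2 groups of 5 libraries each, wild type (WT) and Foxo4 mutant (Foxo4_KO), whose mutation lay on the maternally inherited X chromosome. The replicate numbers 1 to 5 come from the sample titles. The labels do not say whether the 5 libraries of a group came from separate litters or fetuses, so the p-values measure the spread between these libraries, which may in part be technical. No litter, fetal sex or batch is given in the labels. The column headers carry a sequencing lane: WT 5, Foxo4_KO 1 and Foxo4_KO 2 were in lane 1 and the other 7 libraries in lane 2.

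Per the labels' protocols, the authors made libraries from total RNA with a TruSeq RNA kit, sequenced paired ends of 100 bases on an Illumina instrument, and mapped the reads to the rat genome with CLC Genomics Workbench 12.0. Whether the kit marked the strand is not given in the sources used here, so reads of a gene and of another gene on the opposite strand cannot be told apart. The labels name Rnor_5.0 with Ensembl release 78, but the deposited coordinates include a chromosome Y and end at 282724300 on chromosome 1, so the build behind them is uncertain and coordinates are given as deposited. The deposited table holds 1 row per transcript, 33349 transcripts of 26088 genes. For each library, per the file headers, it gives counts of total reads and of unique reads per transcript. It also gives the authors' RPKM. That RPKM was found from the values to use 1 divisor per library, and the reads in the table are 78.8% to 80.4% of it. The labels speak of TPM, a unit the deposited table does not hold. The deposited table also holds the authors' own comparison of the groups as a signed fold score with a p-value and a false discovery rate.

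For the main analysis the deposited counts of total reads were summed over the transcripts of each gene. Total reads per library ran from 19859997 to 22827898, of which 69.6% to 70.8% were unique to 1 transcript. At this depth the spread between libraries exceeds counting error: over the 20 pairs of libraries of the same group, the chi-square per gene ran from 9.98 to 31.2, so no library was a repeat deposit of another. Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), libraries were scaled by TMM, and Foxo4_KO was tested against WT with the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05 over the 13244 genes kept. Levels are TMM-scaled CPM, counts scaled to a common library size, given as mean ± SD with n = 5 per group. Log2 fold changes are Foxo4_KO over WT, with a standard error (SE) computed as the absolute log2 fold change over the square root of F. Foxo4 was also tested with a two-sided exact permutation test on log2 CPM over all splits of the 10 libraries into groups of 5 (SciPy 1.17.1), whose smallest possible p is 0.00794.

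The 35 gene lists, 840 members in all, were fixed before the data were examined, as were the main test and the alternatives named below unless stated otherwise. Of these members, 802 were matched to genes of the table by name, or by a synonym in a RefSeq gene table of the GRCr8 assembly that was used for names only; 18790 of the table's genes have a name found there. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists, and beside it with fry, which asks whether the members of a list move on balance one way, without comparing them with other genes. Genes named in the text follow a rule fixed in advance. It takes Foxo4, then among genes past the threshold with an established symbol and a mean of at least 1 CPM in a group the 12 with the largest rise and the 12 with the largest fall. It adds the 4 members with the smallest p of each list past its test and at most 2 of each other list, and the other FOXO and Akt genes. That gave 114 genes. Of these, 14 have another annotated gene within their span and 4 with a single transcript have under 90% unique reads. Genes outside this rule are named as such.

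Alternatives were DESeq2 size factors (RLE), total counts only, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom with and without quality weights, a block for the replicate number, each library left out in turn, unique reads, and library sizes without erythroid and prolactin genes. Other planned thresholds, list tests and covariates (a Y-linked score and the marker means of decidua, endothelium and labyrinth) were also run. The tests intended on TPM were replaced by limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), summed per gene. These were added after the data were seen, as were the lane as a term, lane 2 alone (4 WT and 3 Foxo4_KO libraries), a fit on transcript reads, and the comparison of folds and SE before and after the covariates. The pipeline was tested on simulated counts for the Foxo4_KO and WT libraries with 200 of 13244 genes changed. Of the simulated genes 13123 passed the filter. The test called 56.7% of those changed 1.5-fold, 79.1% of those changed 2-fold and 92.4% of those changed 4-fold. In that simulation 7 of the 159 calls were of unchanged genes, and no gene was called when none was changed. With 1 list raised 1.5-fold in the simulation, camera called that list and no other. The simulated genes were drawn independently of each other, so this did not test list calls among correlated genes.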

Results

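Junctional zone tissue of gestation day 18.5 was profiled in 5 WT and 5 Foxo4_KO libraries to ask how loss of the forkhead transcription factor Foxo4, a target of the kinase AKT, alters gene expression in this trophoblast compartment. WT libraries held 21575470, 22798836, 20172543, 20805879 and 19859997 reads for replicates 1 to 5, and Foxo4_KO libraries 20396341, 22827898, 20170302, 20630980 and 21203249. Between 16504 and 17171 genes had at least 1 read in a library. The first principal component of the 13244 tested genes carried 45.8% of the variance and separated the groups, while the second, with 11.7%, set Foxo4_KO 1 apart from the other 9 libraries.

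**Figure D1:**
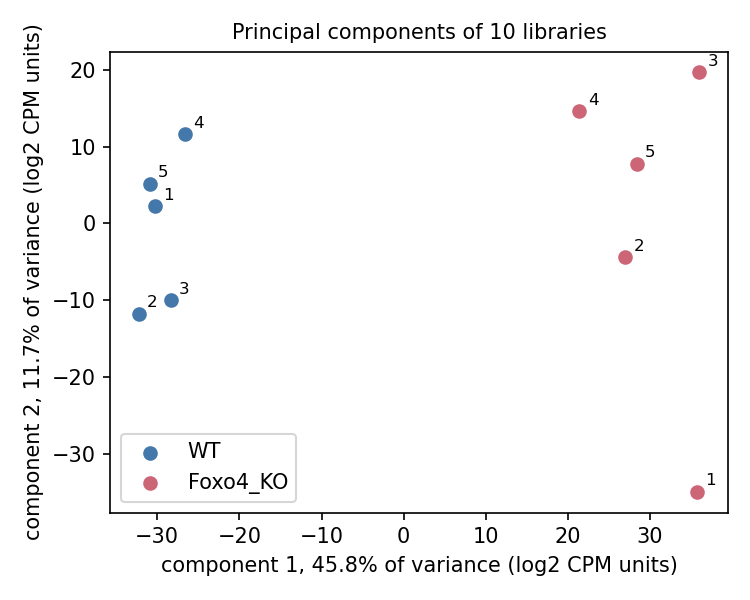
Principal components of log2 CPM for the 10 libraries, with replicate numbers beside the points. Component 1 (45.8% of variance, horizontal axis) separates the 5 WT from the 5 Foxo4_KO libraries, and Foxo4_KO 1 lies far below the others on component 2 (11.7%).

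Reads over Foxo4 (ENSRNOG00000033316, chromosome X, 71155600 to 71162158) remained in the mutant libraries. Its span overlaps the provisional locus Rn50_X_0721.2, and 54.3% of its reads were unique to 1 transcript. Its reads fell from 2222 ± 158 CPM in WT to 1869 ± 182 in Foxo4_KO (SD, n = 5), a log2 fold change of -0.25 ± 0.076 with adjusted p = 0.0181, and every Foxo4_KO library lay below every WT library. The two-sided exact permutation test gave p = 0.00794, the smallest it can give, and 0.0106 after adjustment over the gene and its 3 transcripts. The groups did not overlap at 30.9% of all tested genes, so such separation is not particular to Foxo4. The labels do not state which part of the gene was altered, so these reads cannot show whether it is missing. The build behind the coordinates is uncertain. The largest fall was in the transcript Foxo4_2 (ENSRNOT00000076479, 3 exons, 71155893 to 71160371), which went from 5.42 ± 0.776 CPM in WT to 0.935 ± 0.457 in Foxo4_KO (SD, n = 5), log2 fold change -2.52 ± 0.33 (SE), adjusted p = 0.000252 over transcripts. It had 103 to 138 reads per WT library and 5 to 28 per Foxo4_KO library. The abundant transcript Foxo4_3 fell by 0.39 on the log2 scale (adjusted p = 0.00407), and Foxo4_1, the most abundant, went from 1570 ± 114 to 1379 ± 128 CPM without passing the threshold (adjusted p = 0.0714). These transcripts overlap, so the reads assigned to each depend on the authors' split of shared reads. Counted on unique reads alone, the gene gave -0.09 (adjusted p = 0.373), and in lane 2 alone -0.17 (adjusted p = 0.13), in a range of 0.00421 to 0.696 over all alternatives. Unique reads leave out those shared among the 3 Foxo4 transcripts. They were mostly of Foxo4_1, with 17769 to 20086 per WT library against 4100 to 4517 of Foxo4_3. The smaller fall on unique reads therefore does not show that the fall came from reads shared with other genes.

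**Figure D2:**
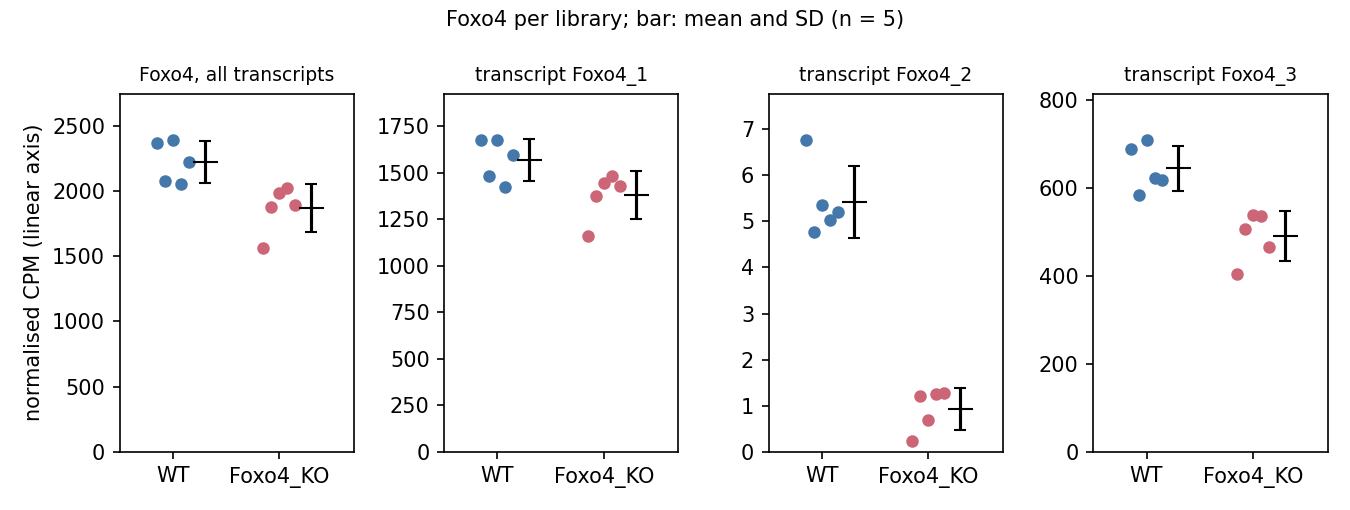
Normalised CPM (linear axis from 0) of Foxo4 and of its 3 annotated transcripts in each of the 5 WT and 5 Foxo4_KO libraries, with mean and SD. The gene goes from 2222 to 1869 CPM, and transcript Foxo4_2 from 5.42 to 0.935 CPM.

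Among the other FOXO and AKT genes Akt2 and Akt3 passed the threshold. Foxo1 (-0.37 ± 0.15, adjusted p = 0.0684), Foxo3 (0.08 ± 0.065, 0.312) and Foxo6 (0.67 ± 0.29, 0.0834) did not pass the threshold. Foxo1 passed with DESeq2 (adjusted p = 0.0407), limma-voom without (0.0458) and with quality weights (0.0396), a mean of at least 5 CPM (0.0451) and without Foxo4_KO 4 (-0.50, 0.00789). Foxo6 passed with the lane as a term (0.71, adjusted p = 0.0437), in lane 2 alone (1.04, 0.0148) and without Foxo4_KO 1 (0.79, 0.0464) or Foxo4_KO 2 (0.83, 0.0292). Akt1 did not pass, at 208 ± 8.81 CPM in WT and 209 ± 11.5 in Foxo4_KO (adjusted p = 0.911). Akt2 fell (-0.46 ± 0.055, adjusted p = 5.37e-05). Akt3 also passed (-0.26 ± 0.092, adjusted p = 0.0389), but its span overlaps Sdccag8 and leaving out WT 1, 2 or 5 or Foxo4_KO 1, 3, 4 or 5 ended the call (log2 fold change -0.26 to -0.20, adjusted p 0.0578 to 0.0926). It also ended in lane 2 alone (-0.26, adjusted p = 0.128), with total counts only (-0.20, 0.0773), no filter (0.053), limma-voom (0.0526) and RPKM (0.0987).

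Mutant and WT junctional zones differed at 5824 of 13244 tested genes (44%), 2851 higher and 2973 lower in Foxo4_KO. The groups did not overlap at 4089 tested genes (30.9%). Most changes were small, with a median absolute log2 fold change of 0.45 among them. Of the 848 that changed at least 2-fold, 214 rose and 634 fell. The largest falls left little expression in Foxo4_KO, several of them from a low level in WT. Amica1, a junctional adhesion protein (chromosome 8, 49378643 to 49410088), fell from 76.7 ± 11.6 to 2.03 ± 0.584 CPM (-5.24 ± 0.18, adjusted p = 2.14e-08). The receptor tyrosine kinase Erbb3 fell from 45.1 ± 7 to 3.45 ± 0.495 CPM (-3.70 ± 0.13, adjusted p = 5.9e-09), and Grb7, an adaptor that binds ERBB receptors, from 12.6 ± 1.87 to 1.4 ± 0.364 CPM (-3.16 ± 0.17). Amn, a partner of cubilin in endocytosis (-3.54 ± 0.31), Nphs1, which encodes nephrin (-3.97 ± 0.39), Nsg1 (-3.44 ± 0.34), Atp8b3 (-3.20 ± 0.38), Gpbar1, a bile acid receptor (-3.95 ± 0.35), Fam26f (-3.81 ± 0.34) and Me3, a mitochondrial malic enzyme (-3.83 ± 0.51), had WT means under 10 CPM and fell in all 5 Foxo4_KO libraries, below every WT library. Of these, Me3 (1.14 CPM in WT), Fam26f (1.39), Gpbar1 (1.39) and Atp8b3 (1.78) lay near the 1 CPM needed for naming, so the size of their falls is uncertain. Over the alternatives their smallest log2 fold changes were -0.50, -0.82, -0.96 and -0.34. Me3 was -4.82 without Foxo4_KO 4. Atg9b (-3.32 ± 0.29) had 99.6% unique reads, and an end of its span overlaps that of Nos3, which also fell. RT1-DMa_1 (-3.86 ± 0.83) had no unique reads, and its value rests on Foxo4_KO 3, since it was -8.68 without that library, a fitted value that is no bound.

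The largest rises were of genes with low expression in WT. Nol4 rose from 0.206 ± 0.0869 to 1.93 ± 0.662 CPM (3.20 ± 0.34, adjusted p = 2.64e-05), Gdf10, a TGF-beta family growth factor, from 1.5 ± 0.812 to 11.3 ± 5.67 CPM (2.91 ± 0.42) and B4galnt1, a ganglioside synthase, from 3.47 ± 1.01 to 12.3 ± 1.71 CPM (1.83 ± 0.18, in a span shared with Slc26a10). The ligand Wnt3 (1.87 ± 0.21), the keratin Krt15 (2.75 ± 0.37), the mitotic entry factor Cdca3 (2.04 ± 0.37), the T-cell kinase Itk (2.00 ± 0.30), Doc2b (2.58 ± 0.67), Rgs22 (2.26 ± 0.27), Tmem130 (1.95 ± 0.53), Lingo1 (1.87 ± 0.27) and Megf11 (1.84 ± 0.39) also rose, each in all 5 Foxo4_KO libraries. In lane 2 alone the call of Tmem130 ended (1.92, adjusted p = 0.0777). Doc2b was 1.89 without Foxo4_KO 3, and Megf11 2.42 without WT 4. All values are from the edgeR quasi-likelihood test. Leaving out each library in turn gave 5256 to 5620 genes, 5562 without Foxo4_KO 1, and 4351 genes passed in lane 2 alone. Endothelial and decidual markers were lower in Foxo4_KO, and with the endothelial marker mean as a covariate 854 genes passed, with the decidual mean 1317. Among the 5013 calls that ended with the endothelial covariate, the median absolute log2 fold change went from 0.42 to 0.38 and the median SE from 0.0915 to 0.211. Among the 4604 that ended with the decidual one these went from 0.40 to 0.29 and from 0.0919 to 0.168.

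**Figure D3:**
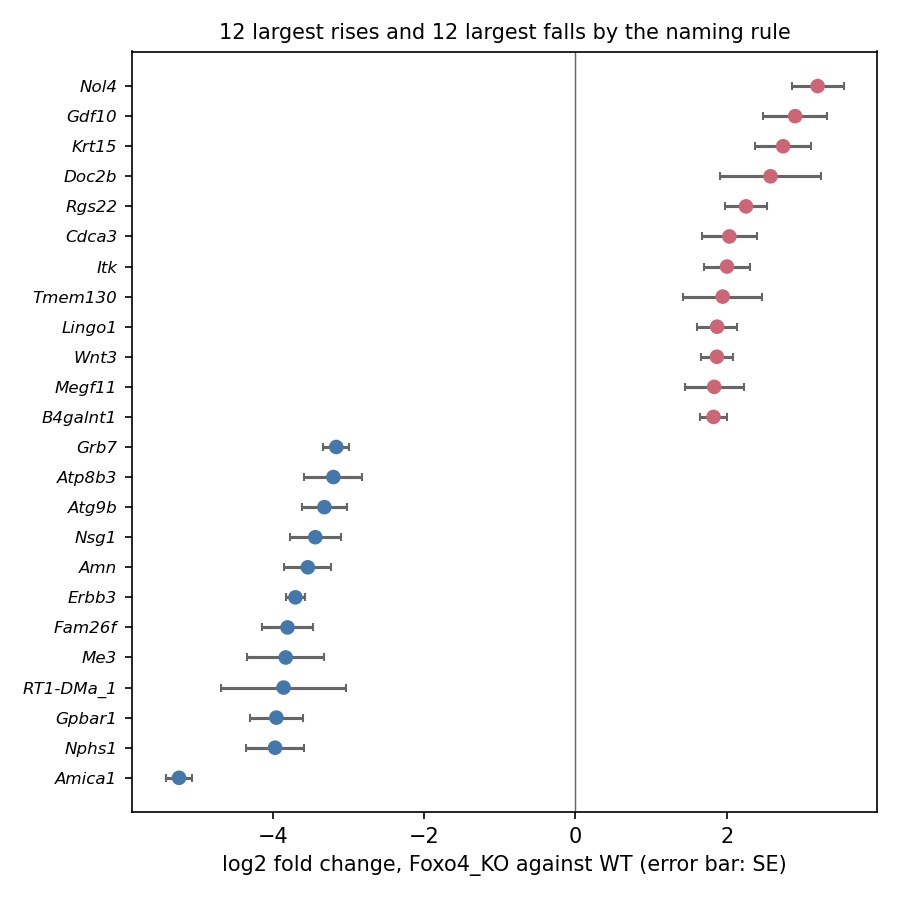
Log2 fold change (Foxo4_KO over WT, horizontal axis) with its SE for the 12 largest rises and 12 largest falls taken by the naming rule. Falls reach -5.24 (Amica1) and rises 3.20 (Nol4).

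Of the 34 gene lists tested, 11 passed camera with the preset correlation, 1 higher and 10 lower in Foxo4_KO. None passed with a correlation estimated from the residuals, where the adjusted p of those 11 ran from 0.42 to 0.696, so the list calls rest on the preset value. By fry, 18 lists moved on balance in 1 direction. Beyond those past camera, these included matrix proteases (fry adjusted p = 0.00496), cholesterol synthesis (0.0117) and invasive trophoblast markers (0.0142). Pregnancy-specific glycoproteins and CEACAMs (fry adjusted p = 0.04445), nutrient transporters (0.0446) and the mesenchymal and early response lists given below were the others. In regroupings of the libraries, 13 of 100 splits gave at least 11 lists, the real one included. Endothelial markers (median -0.80), decidual markers (-0.65) and mitochondrial transcripts (-0.43) fell in the same Foxo4_KO libraries in which the other lists below moved. The early response list was chosen to track tissue handling, but its level need not come from handling. Its mean was 4.824 to 5.248 log2 CPM in Foxo4_KO and 4.686 to 4.758 in WT libraries. The list passed fry (adjusted p = 0.0375) but not camera (adjusted p = 0.211). Other list means also separated the groups, such as cell cycle, at 2.908 to 3.095 in Foxo4_KO and 2.206 to 2.454 in WT libraries. With genes of at least 5 CPM on average, the calls ended for endothelial markers (median -0.49 over 6 members, adjusted p = 0.162), angiogenic factors (-0.47, 0.0892), decidual markers (-0.79, 0.0892) and AKT and insulin/IGF signalling (-0.18, 0.0632), and the yolk sac list was too short to test. In lane 2 alone they ended for AKT and insulin/IGF signalling (-0.22, adjusted p = 0.0609) and decidual markers (-0.51, 0.0507). With the decidual covariate they ended for AKT and insulin/IGF signalling (-0.21, adjusted p = 0.0788), angiogenic factors (-0.20, 0.966), endothelial markers (-0.30, 0.0925) and decidual markers (-0.001374, 0.977). With the endothelial one they ended for those lists (-0.19, 0.0752; -0.13, 0.751; -0.04, 0.889; -0.37, 0.543) and yolk sac markers (-1.10, 0.0645). With the labyrinth one they ended for AKT and insulin/IGF signalling (-0.21, adjusted p = 0.0574), angiogenic factors (-0.40, 0.0574) and decidual markers (-0.54, 0.113). A list's own marker mean as covariate removes its fall by construction, and angiogenic factors share members with endothelial markers. The endothelial mean correlated with the group at -0.903 and the decidual mean at -0.854, so the calls that ended do not show a cause.

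Cell cycle genes rose. Of 39 tested members 29 were higher, 3 lower and 7 did not pass, with the same counts when adjusted over the list alone (median log2 fold change 0.74, camera adjusted p = 1.91e-09, adjusted p = 0.42 with an estimated correlation). The proliferation marker Mki67 went from 10.9 ± 2.25 to 28.2 ± 1.56 CPM (1.36 ± 0.12), Top2a, the topoisomerase of dividing cells, from 2.85 ± 0.398 to 6.93 ± 0.988 (1.28 ± 0.14; 12.2% unique reads, and 0.93 with adjusted p = 0.0709 on these alone), the mitotic kinase Cdk1 from 11.6 ± 0.976 to 21.9 ± 1.97 (0.92 ± 0.081) and the replication helicase subunit Mcm3 from 14.9 ± 1.58 to 26.5 ± 2.54 CPM (0.82 ± 0.087). The 3 that fell, chosen after their values were seen, were Cenpf (-0.84), Rrm1 (-0.75) and E2f1 (-0.37).

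Textbook FOXO targets were lower on balance. Of 33 tested, 20 fell, 4 rose and 9 did not pass, and adjusted over the list alone 21 fell and 4 rose (median -0.46, camera adjusted p = 0.000803, adjusted p = 0.458 with an estimated correlation). The insulin receptor substrate Irs2 fell from 117 ± 8.37 to 46.8 ± 4.61 CPM (-1.32 ± 0.072), the insulin receptor Insr from 40.4 ± 1.87 to 21.7 ± 1.42 (-0.89 ± 0.058), the cyclin-dependent kinase inhibitor Cdkn1b from 39.7 ± 1.84 to 22.4 ± 1.47 (-0.82 ± 0.057) and the MYC antagonist Mxi1 from 71.7 ± 5.87 to 33.6 ± 3.47 CPM (-1.09 ± 0.078). The 4 that rose, chosen after their values were seen, were Ccnd1 (0.83), Atg12 (0.26), Cited2 (0.26) and Sesn3 (0.27). In AKT and insulin/IGF signalling, which shares Irs2 and Insr with that list, and also Eif4ebp1 (-0.35) and Rictor (-0.41), chosen after their values were seen, 14 of 31 tested members fell, 6 rose and 11 did not pass, with the same numbers adjusted over the list alone (median -0.24, camera adjusted p = 0.0274, adjusted p = 0.458 with an estimated correlation). The IGF1 receptor Igf1r fell from 11 ± 1.02 to 3.12 ± 0.308 CPM (-1.81 ± 0.10, adjusted p = 3.08e-07) and the PI3-kinase subunit Pik3ca by 0.60 on the log2 scale (adjusted p = 9.07e-06, with 73.3% unique reads).

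Autophagy and lysosome genes were lower, with 17 of 29 falling and 5 rising, also when adjusted over the list alone (median -0.26, camera adjusted p = 0.00431, adjusted p = 0.531 with an estimated correlation). Gabarapl2, an autophagosome protein (-0.79 ± 0.058), the initiating kinase Ulk1 (-0.68 ± 0.056), and the lysosomal enzymes Hexb (-0.67 ± 0.06) and Ctsd (-0.80 ± 0.10) fell. The 5 that rose, chosen after their values were seen, were Atg12, Tfeb (0.43), Neu1 (0.47), Atg3 (0.14) and Atg4b (0.14). In antioxidant defence 18 of 38 fell and 4 rose, or 19 and 5 adjusted over the list alone (median -0.26, camera adjusted p = 0.013, adjusted p = 0.531 with an estimated correlation). The glutathione synthetase Gss (-0.68 ± 0.079), the glutathione transferase Gstm1 (-0.86 ± 0.12) and mitochondrial thioredoxin Txn2 (-0.50 ± 0.056) fell, whereas thioredoxin reductase Txnrd1 rose (0.56 ± 0.05), as did Gclm (0.21), Prdx3 (0.17) and Gstp1 (0.33), chosen after their values were seen. Interferon response genes fell in 10 of 24 cases and rose in none, 12 and none adjusted over the list alone (median -0.42, camera adjusted p = 0.000596, adjusted p = 0.696 with an estimated correlation). Rsad2 (-1.65 ± 0.14), the RNA sensor Ddx58 (-0.83 ± 0.16), the MHC class I light chain B2m (-0.43 ± 0.057) and the locus Ifitm3_1 (-0.95 ± 0.16) fell.

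Markers of other tissues moved with the groups. Endothelial markers were lower, 11 of 14 falling and 1 rising, or 12 and 1 adjusted over the list alone (median -0.80, camera adjusted p = 0.00277, adjusted p = 0.458 with an estimated correlation), among them Ramp2 (-1.21 ± 0.17), the phosphatase Ptprb (-1.08 ± 0.19), Tie1 (-0.94 ± 0.20) and the VEGF receptor Kdr (-0.40 ± 0.092). The member that rose was Esam (0.30), chosen after its value was seen. Angiogenic factors, 9 of 22 falling and none rising either way of adjusting, shared Tie1 and Kdr with them, and also Eng (-0.52) and Tek (-1.44), chosen after their values were seen (median -0.50, camera adjusted p = 0.013, adjusted p = 0.531 with an estimated correlation). Nos3 (-1.36 ± 0.23) and Angpt4 (-0.81 ± 0.16) fell as well. Decidual and uterine stroma markers were lower, 8 of 15 falling and 1 rising, or 9 and 1 adjusted over the list alone (median -0.65, camera adjusted p = 0.0274, adjusted p = 0.531 with an estimated correlation; camera adjusted p = 0.0568 without WT 4). The transcription factors Hand2 (-1.34 ± 0.18), Hoxa10 (-0.89 ± 0.18) and Hoxd10 (-0.91 ± 0.22) fell, while Prl8a2, the decidual prolactin-related protein, rose from 3936 ± 519 to 6275 ± 574 CPM (0.67 ± 0.094). Of 5 tested yolk sac endoderm markers 4 fell on either adjustment, Amn, Lrp2 (-1.48 ± 0.24), Cubn (-1.24 ± 0.37, with 9.89% unique reads) and Apoa4 (-0.66 ± 0.18, with 67.9% unique reads), with a median of -1.24 (camera adjusted p = 0.0257, adjusted p = 0.42 with an estimated correlation). In lane 2 alone the calls of Cubn (-0.77, adjusted p = 0.11) and Apoa4 (-0.53, 0.0814) ended. With no low-count filter all 20 matched members were tested and the call ended (median -0.25, camera adjusted p = 0.137). That list also fell short without WT 1, 3, 4 or 5 or Foxo4_KO 3 or 4 (medians -0.82 to -0.61, camera adjusted p 0.0584 to 0.132). These refits tested 6 or 7 members, since the filter was applied anew, so their medians do not cover the same members as the -1.24 over 5. Mesenchyme and pericyte markers had a median of -0.56, with 6 of 16 falling and 2 rising, or 7 and 2 adjusted over the list alone. They did not pass camera (adjusted p = 0.0805) but passed fry (adjusted p = 0.00608).

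All 11 tested mitochondrially encoded transcripts fell, also when adjusted over the list alone (median -0.43, camera adjusted p = 1.66e-05, adjusted p = 0.458 with an estimated correlation). Mt-nd1, a subunit of complex I, went from 1783 ± 121 to 1246 ± 77.1 CPM (-0.52 ± 0.062). Mt-nd4 (-0.64 ± 0.085) overlaps Mt-nd4l (-0.68 ± 0.087), and Mt-nd6 (-0.46 ± 0.059) overlaps the end of Mt-nd5. The 41 nuclear genes of oxidative phosphorylation had a median of -0.06, with 4 higher and 10 lower, or 1 and 9 adjusted over the list alone, and did not pass camera (adjusted p = 0.228).

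**Figure D4:**
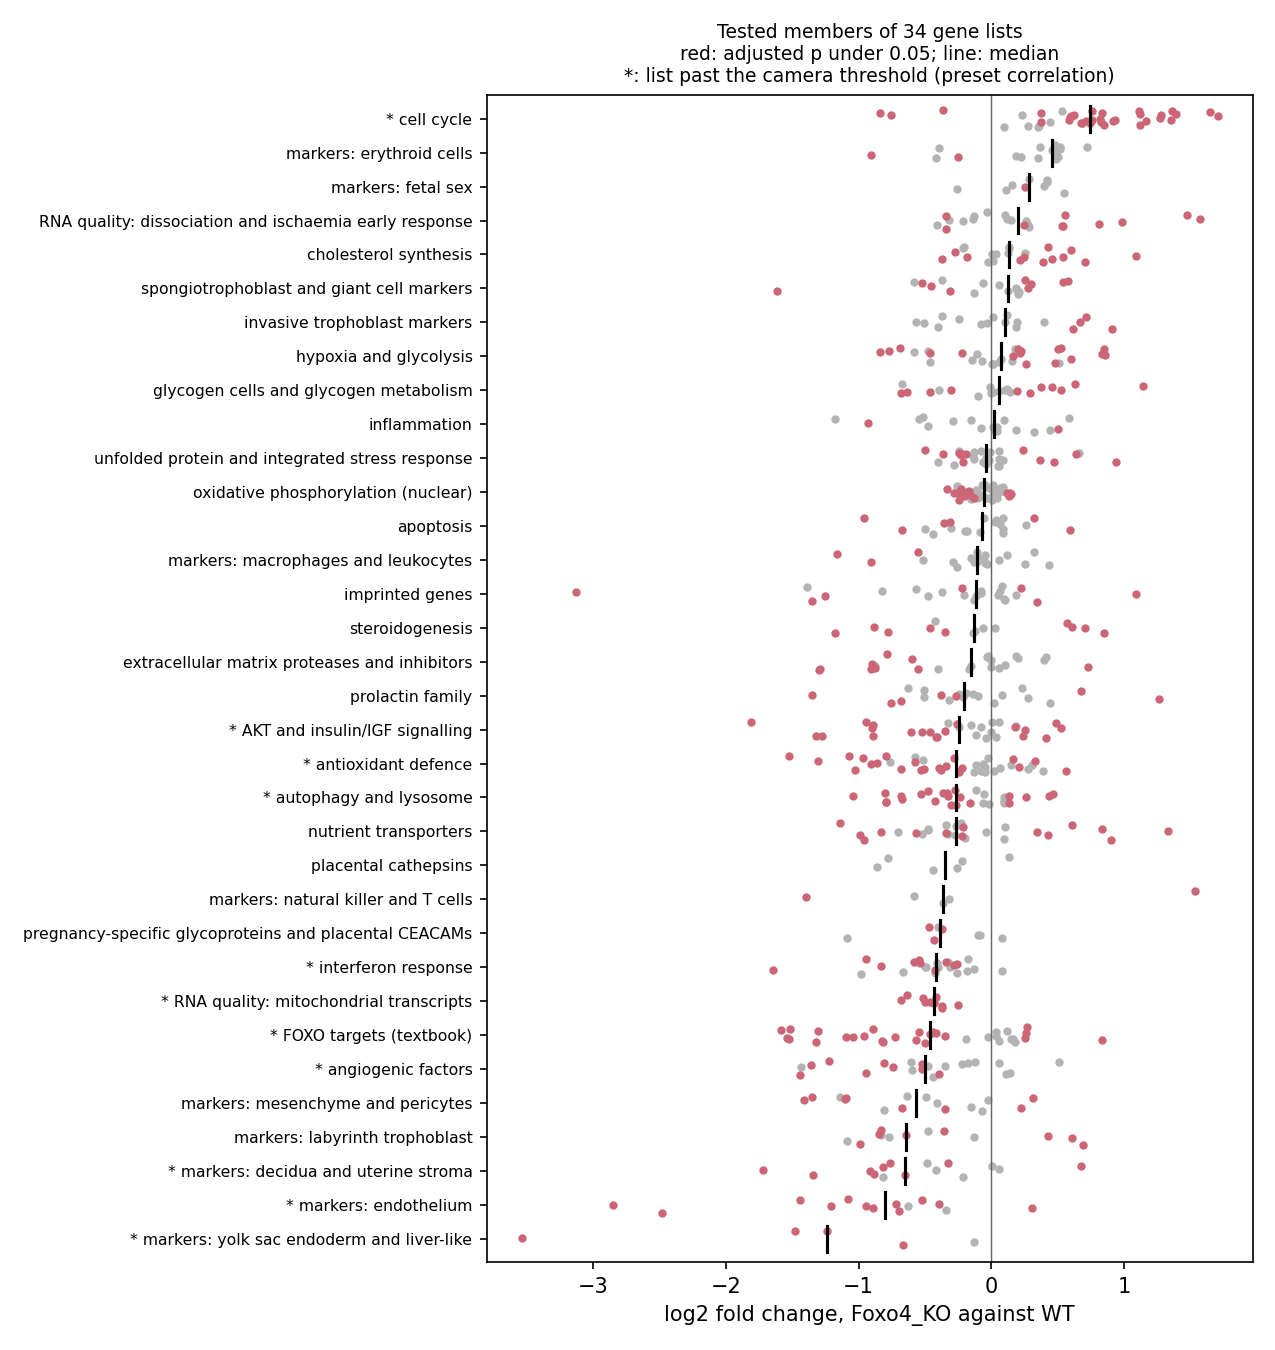
Log2 fold change (Foxo4_KO over WT, horizontal axis) of each tested member of the 34 lists, red where the gene passed the adjusted threshold, with the list median as a black line and an asterisk for the 11 lists past camera with the preset correlation. The cell cycle median is 0.74 and the endothelial median -0.80.

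Because Foxo4 is X-linked and the mutation came through the mother, X-linked and neighbouring genes were examined. Of 414 tested X-linked genes 174 passed (42%), 97 higher and 77 lower, against 5638 of 12811 autosomal genes (44%). The odds ratio was 0.922 with a 95% interval of 0.752 to 1.13 (Fisher's exact test, two-sided p = 0.451). With no low-count filter it was 0.8001 (Fisher's exact test, p = 0.0117), and at a mean of at least 5 CPM 1.145 (p = 0.303). Within 1 Mb of Foxo4, 20 other genes were tested and 8 passed, 7 of them higher. Immediately beyond its end lie Il2rg, a cytokine receptor chain (0.45 ± 0.072), and Med12, a Mediator subunit (0.75 ± 0.056, adjusted p = 2.66e-06), both higher. Farther away Zmym3 (0.55 ± 0.069), Nono (0.26 ± 0.048), Dlg3 (0.57 ± 0.059), the kinesin Kif4a (1.69 ± 0.25) and Ercc6l (1.21 ± 0.35) were higher. The provisional locus LOC102548326 before its start was lower (-0.97 ± 0.20).

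**Figure D5:**
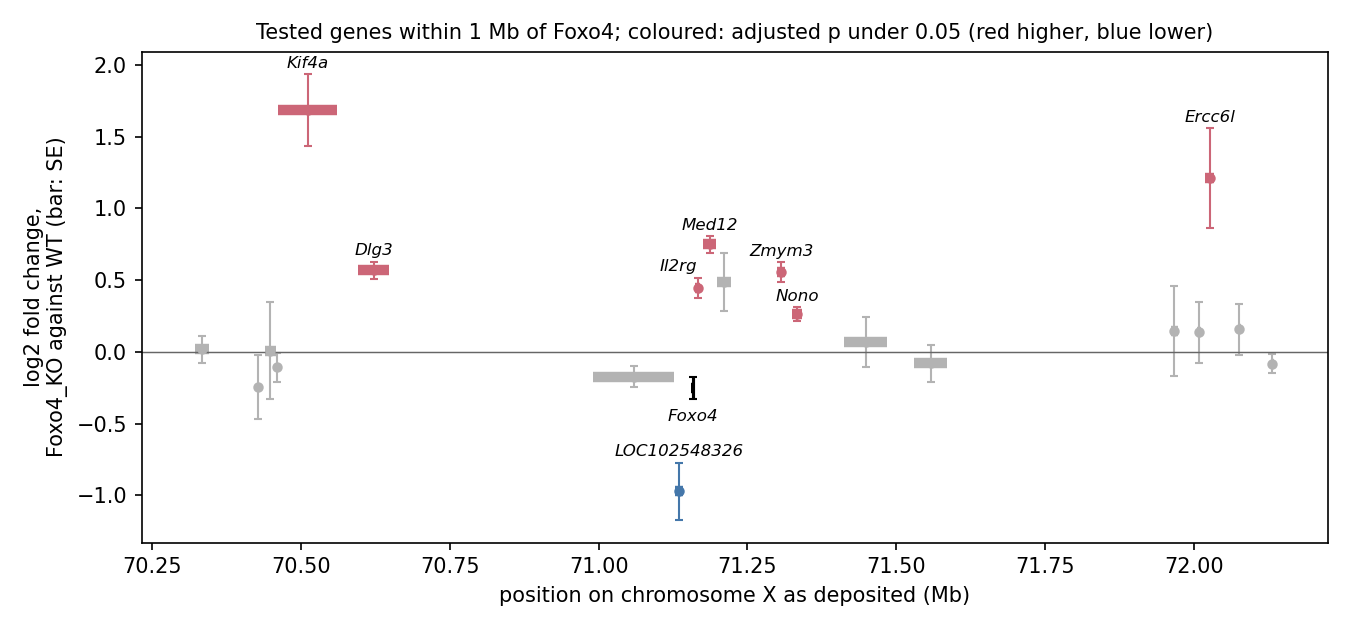
Log2 fold change with SE (vertical axis) of Foxo4, in black, and of the 20 tested genes within 1 Mb, drawn to scale along chromosome X in Mb as deposited (horizontal axis). The 7 neighbours higher in Foxo4_KO are red, the 1 lower is blue and those that did not pass are grey.

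The authors' deposited table, which compares transcripts, has 1409 at p under its cutoff of 0.05, of 1324 genes. Of these genes 1233 (93.1%) also passed here in the same direction. At a deposited false discovery rate under 0.05 the authors' deposited table has 487 transcripts, 157 higher and 330 lower, of 467 genes, and 460 of these (98.5%) passed here in the same direction. Another 4589 genes passed here without a transcript under that p. In the edgeR fit on transcript reads 5874 of 16281 tested transcripts passed. Over the 10795 transcripts with a mean of at least 100 reads, the fold changes in the authors' deposited table and those of the read totals had a Pearson correlation of 0.998 across transcripts, which are not independent replicates. A p of 1 stands beside 59.7% of the transcripts that the authors deposited.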

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

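None of the tests in this part was chosen after the result was seen. In 13 of 314 sets of 5 values 1 library lay far from the other 4 of its group, where chance alone would give about 15.7, and no library had more than 3 of them. Values are log2 CPM. Among Foxo4_KO libraries, replicate 1 was lowest for Cspg4 (4.51, others 5.22 to 5.5) and Tie1 (1.88, others 2.93 to 3.2), replicate 3 was highest for RT1-DMa_1 (-0.0811, others at the floor of -3.39), and replicate 4 was highest for Angpt4 (2.36, others 1.76 to 1.92) and for the mean of the matrix protease list (5.48, others 5.27 to 5.32). Replicate 5 of that group was lowest for Slco2a1 (5.93, others 6.39 to 6.54) and Sqle (5.39, others 5.5 to 5.52) and highest for Cox6c (5.71, others 5.54 to 5.59). Among WT libraries, replicate 5 was highest for Epcam (6.54, others 6.29 to 6.32), and replicate 4 for Ramp2 (2.48, others 2.02 to 2.15) and Slc22a3 (1.67, others -0.239 to 0.035). WT replicate 2 was lowest for Foxo6 (0.509, others 1.35 to 1.6) and highest for Cd68 (6.84, others 6.65 to 6.69).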

How the results depend on the processing

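Of 3634 values recomputed under the alternatives, 3376 were kept, 192 lost a call, 20 gained one, 18 turned and 28 counts or shares moved. A value was kept if its direction and side of the threshold stayed, except for counts and the share of deposited calls. A count was kept within a factor of 1.5 of its main value, and that share inside its 95% interval (91.63% to 94.43%). Settings with RPKM, lane and transcripts were chosen after the data were seen, as were the covariates for every result but the number of changed genes. So were all alternatives for the deposited comparison except its false discovery rate, and for the X chromosome and the neighbours except an unadjusted p and the 5 Mb window. The tests intended on TPM were not run as such. The cause was not tested for the changes below except where the setting itself gives it.

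The number of changed genes ran from 4351 in lane 2 alone to 6814 at an unadjusted p, apart from 1317 with the decidual and 854 with the endothelial marker mean as covariate, where the SE of the ended calls rose more than their fold fell, and 2143 at a fold of at least 1.5, a stricter rule. Each of the 10 leave-outs gave 5256 to 5620. With total counts only, 57.8% of calls were higher and with RPKM 58.9%, against 49%, and the median over all genes was at most 0.0535. Foxo4 lost its call on unique reads (-0.08751), in lane 2 alone (-0.1716) and with the decidual (-0.1148) and endothelial (-0.1322) covariates, and ran from -0.2773 to -0.1894 over the leave-outs.

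The 11 lists of 34 became 6 of 32 at a mean of at least 5 CPM, where 4 of the 11 lost their call and the yolk sac list was too short to test, as it was on unique reads (10 of 32). They became 0 with an estimated correlation, 18 by fry and 9 to 12 over the leave-outs. Of the 11, 7 kept their call with the decidual covariate, 6 with the endothelial and 8 with the labyrinth one. Under its own covariate, which by construction removes it, the decidual list had a median of -0.001374, still below 0, and it counts among the 18 because the direction of camera changed to up (adjusted p = 0.977).

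The labels do not say whether the replicate numbers pair the libraries. The values gave little sign of pairing, which does not exclude it. Same-numbered libraries had deviations correlated from -0.1164 to 0.1683, above 0.1 for 1 of 5 numbers, and 2 of 5 WT libraries correlated best with their own number. With the replicate block 5557 genes, 12 lists and Foxo4 (-0.2519, adjusted p = 0.03812) passed, as did Foxo1 (-0.38, adjusted p = 0.0172) and Foxo6 (0.63, 0.0203).

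The share of deposited calls found here (93.1%) became 90.4% with no filter, 89.7% with at least 5 CPM, 95.1% with DESeq2, 88.1% on unique reads, 37.9% with the decidual, 27.3% with the endothelial and 84.7% with the labyrinth covariate, 91.2% with the lane as a term, 83.2% in lane 2 alone, 98.5% at a deposited false discovery rate, and 89.65% to 91.69% over the leave-outs. The X-linked odds ratio was 0.8001 with no filter, where it passed (Fisher's exact p = 0.0117, up to 0.833 over the alternatives), and 1.145 at 5 CPM; it ran from 0.8878 to 0.9683 over the leave-outs. Neighbours of Foxo4 past the threshold numbered 3 with the decidual and 3 with the endothelial covariate, 21 of 50 within 5 Mb, and 8 to 10 over the leave-outs.

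Of 113 named genes 44 kept direction and call under each setting that gave them a value; 84 of the 113 had one at 5 CPM and 107 on unique reads. No gene below passed the threshold in its turned direction. Akt1 was -0.02123 at 5 CPM, -0.006246 on unique reads, -0.02234, -0.05047 and -0.005137 with the decidual, endothelial and labyrinth covariates, -0.003264 in lane 2, and -0.02117 to 0.0398 over the leave-outs. Under the decidual covariate Foxo1 was 0.2531 and Ddx3x -0.007964. Under the endothelial covariate Foxo1 was 0.2828, Tie1 0.002765, Cts8l1 1.135 and Eif2s3 -0.1339, and under the labyrinth covariate Cts8l1 was 0.01088. In the simulation, where 200 of 13244 genes were changed, 56.7% of 1.5-fold changes were called. In the data 5824 genes passed, so the adjustment was less strict there and that share does not carry over.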

Other observations

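Tests of the sequencing lane on the gene count, of a common fall of marker genes and of the nuclear respiratory genes were chosen after the result was seen; the others in this part were written before theirs.

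Lists that did not pass camera also held genes past the threshold. Of all 13244 tested genes 44% passed, 2851 higher and 2973 lower, so the counts below alone say nothing particular about a list. The keratins Krt19 (0.91 ± 0.069, with 66.7% unique reads) and Krt18 (0.72 ± 0.076) of the invasive trophoblast list rose to 1118 ± 93.6 and 2665 ± 294 CPM (SD, n = 5), in a list with 4 of 17 higher and 0 lower, 4 and 0 adjusted over the list alone (adjusted p = 0.186). The spongiotrophoblast and giant cell list had 5 of 19 higher and 4 lower, 5 and 4 adjusted over the list alone (adjusted p = 0.772), with a median of 0.13, a mean of -0.06 and camera's direction up. The prostaglandin transporter Slco2a1 fell from 250 ± 44.4 to 81.8 ± 12.2 CPM (-1.61 ± 0.14) and the trophoblast factor Tfap2c rose (0.28 ± 0.043). The prolactin family had 2 of 22 higher and 5 lower, 2 and 5 adjusted over the list alone (adjusted p = 0.443), with Prl8a2 higher and Prl7a3 lower (-0.75 ± 0.11). Pregnancy-specific glycoproteins and CEACAMs had 0 of 8 higher and 3 lower, 0 and 3 adjusted over the list alone (adjusted p = 0.211), including Ceacam11 (-0.47 ± 0.11) and Psg29 (-0.43 ± 0.12), whose calls ended in lane 2 alone (-0.44, adjusted p = 0.0604, and -0.46, 0.0596). Placental cathepsins had 0 of 6 higher and 0 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.561). Testin (-0.86 ± 0.34) and Cts8l1 (-0.78 ± 0.37) had the smallest p among them, and Testin passed with DESeq2 (adjusted p = 0.0244), with the replicate block (0.00809), and without WT 3 (-0.97, adjusted p = 0.0475), WT 4 (-0.9998, 0.0325) or Foxo4_KO 2 (-1.14, 0.0155). Steroidogenesis had 4 of 14 higher and 5 lower, 4 and 5 adjusted over the list alone (adjusted p = 0.662), with Cyp11a1, the enzyme that starts steroid synthesis, rising to 332 ± 37.7 CPM (0.85 ± 0.10) and Stard3 falling (-0.35 ± 0.058). Cholesterol synthesis had 9 of 22 higher and 3 lower, 10 and 3 adjusted over the list alone (adjusted p = 0.0659), with rises of Sqle (0.54 ± 0.054) and Dhcr24 (1.09 ± 0.14).

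The glucose transporter Slc2a1 rose to 1464 ± 144 CPM (0.83 ± 0.069), while the hypoxia and glycolysis list had 12 of 31 higher and 5 lower, 12 and 5 adjusted over the list alone (adjusted p = 0.211), with Aldoc lower (-0.84 ± 0.093), and nutrient transporters 6 of 27 higher and 8 lower, 6 and 10 adjusted over the list alone (adjusted p = 0.335), with Slc38a2 lower (-0.34 ± 0.037). Glycogen genes had 7 of 21 higher and 4 lower, 7 and 4 adjusted over the list alone (adjusted p = 0.51), among them falls of Phkb (-0.64 ± 0.071) and Pgm2 (-0.68 ± 0.08). Imprinted genes had 3 of 23 higher and 4 lower, 3 and 4 adjusted over the list alone (adjusted p = 0.51), with Slc22a18 (-1.25 ± 0.09) and Slc22a3 (-3.13 ± 0.54, -2.48 without WT 4) lower. The unfolded protein and integrated stress list had 5 of 32 higher and 7 lower, 5 and 7 adjusted over the list alone (adjusted p = 0.842), with Asns (0.64 ± 0.085) and Dnajb9 (0.37 ± 0.059) higher, and its median of -0.04, beside a mean of 0.0025, became 0.01 with total counts only. Apoptosis had 2 of 20 higher and 4 lower, 2 and 4 adjusted over the list alone (adjusted p = 0.652), with Casp6 higher (0.59 ± 0.093) and Bcl2l11 lower (-0.96 ± 0.19), a call that ended on log2(RPKM + 1) (-0.14, adjusted p = 0.207) and on log2(RPKM + 0.1) (-0.37, 0.196). Matrix proteases had 1 of 23 higher and 8 lower, 1 and 8 adjusted over the list alone (adjusted p = 0.174), with Adamts9 higher (0.73 ± 0.094) and Mmp19 lower (-0.91 ± 0.10), and inflammation 1 of 18 higher and 1 lower, 1 and 1 adjusted over the list alone (adjusted p = 0.857), Cebpb (0.51 ± 0.047) and Icam1 (-0.93 ± 0.16), with a median of 0.02 and a mean of -0.10. Labyrinth markers had 3 of 13 higher and 5 lower, 3 and 8 adjusted over the list alone (adjusted p = 0.211), with Epcam (-0.64 ± 0.053) and Cebpa (-0.83 ± 0.13) lower. Macrophage markers had 0 of 20 higher and 3 lower, 0 and 2 adjusted over the list alone (adjusted p = 0.494), with Cd14 (-1.16 ± 0.17) and Cd68 (-0.91 ± 0.17), erythroid markers, whose median was 0.46, mean 0.23 and camera direction up, 0 of 17 higher and 2 lower, 0 and 1 adjusted over the list alone (adjusted p = 0.51), Gypc (-0.91 ± 0.16) and Tspan33 (-0.25 ± 0.092), and natural killer and T cell markers 1 of 5 higher and 1 lower, 1 and 1 adjusted over the list alone (adjusted p = 0.842), Eomes (1.53 ± 0.20) and Prf1 (-1.40 ± 0.43). The call of Prf1 ended without WT 2 (-0.9992, adjusted p = 0.0651) and on log2(RPKM + 1) (-0.23, 0.0506), and that of Tspan33 with no filter (adjusted p = 0.0566), total counts only (0.132), the lane as a term (0.0625), RPKM (0.148), lane 2 alone (0.216) and without WT 2 or 5 or Foxo4_KO 1, 2 or 3 (-0.25 to -0.18, adjusted p 0.0701 to 0.12). Among mesenchymal markers Cspg4 (-1.10 ± 0.16) and Pdgfra (-0.35 ± 0.063) fell. The fetal sex list had 1 of 9 higher and 0 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.652), Eif2s3 (0.25 ± 0.082), whose call ended without WT 1, 3 or 4 or Foxo4_KO 1 or 5 (0.20 to 0.23, adjusted p 0.0542 to 0.0757), at 5 CPM (0.22, 0.051) and in lane 2 alone (0.25, 0.0564). Ddx3x did not pass (0.11 ± 0.053), except with total counts only (0.16, adjusted p = 0.0419) and RPKM (0.17, 0.0261). The mean of that list set WT 2 and 5 and Foxo4_KO 1 and 5 (1.268 to 2.656 log2 CPM) apart from the other 6 libraries (4.507 to 5). Libraries of both levels thus occurred in both groups, as would be seen if each group held fetuses of both sexes, which the labels do not state. With a Y-linked score as a covariate 5846 genes passed. The FOXO family list had 3 tested members, none past the threshold, and was too short to test. The early response list had 8 of 22 higher and 2 lower, 8 and 3 adjusted over the list alone (adjusted p = 0.211), with Fosl1 (0.56 ± 0.068) and Myc (0.99 ± 0.12) higher.

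For the number of changed genes a random grouping of these libraries was argued against. The real grouping gave 5824. Of 100 splits drawn from all divisions of the libraries into groups of 5 only the real one (1) gave as many, and the highest other split gave 8. The other splits mix WT and Foxo4_KO libraries, which itself lowers their counts. A litter or handling difference between the groups would give the same result, so the splits cannot tell it from the genotype. The lane was argued against as the whole cause, since 5570 genes passed with the lane as a term. For the number of lists past camera with the preset correlation chance was not excluded. The real grouping gave 11, 13 of the 100 splits gave at least as many, and the highest other gave 15. Other groupings of these libraries thus also pass lists with that preset.

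The first pattern is the lower level of endothelial and decidual markers in Foxo4_KO, beside a mesenchymal list that did not pass camera (adjusted p = 0.0805). The lane was argued against, since within lane 2 the highest of these 3 list medians was -0.514. Less adjoining vessel as the whole cause would lower the endothelial markers by a common factor if all their reads came from vessel. The 14 members, 4 of them also on other lists, differed beyond their errors (Cochran Q = 154, bound 22.4). Reads of these markers from the junctional zone itself would also make the falls unequal, so this cannot exclude less vessel as the whole cause. Cdh5, the most abundant at 223 CPM in WT and chosen after its values were seen, was at 176 in Foxo4_KO without passing, and Esam rose. For decidua and uterine stroma the 15 members also differed (Cochran Q = 197, bound 23.7), with the same limit. Prl8a2, the most abundant of them, rose, but it is also on the prolactin list and its reads need not come from decidua. How much adjoining tissue contributed, beside changes within the junctional zone, stays open. The 854 genes past the threshold with the endothelial covariate decide nothing about it, since the covariate differs between the groups and the SE rose with it.

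The second pattern is the fall of mitochondrially encoded transcripts. Foxo4_KO 1 stood apart by Hspa1b, named after its values were seen, at 233.5 CPM against 43.86 to 66.08 in the other Foxo4_KO libraries, but without it the list median was -0.432. Reads shared with nuclear copies were argued against by a median of -0.447 on unique reads. A fall shared alike by the nuclear respiratory genes was argued against by their median, which lay 0.377 above the mitochondrial one (bootstrap standard error 0.0509). That bootstrap resampled genes as if independent, so its error does not measure the spread between libraries. RNA quality and handling stay open, since no integrity value is given in the sources used here and the early response list was higher in every Foxo4_KO library (mean 4.824 to 5.248 log2 CPM) than in any WT library (4.686 to 4.758) and passed fry (adjusted p = 0.0375) but not camera (0.211). Separate means are not particular to the early response list, since those of the cell cycle list did not overlap either. An effect of the genotype on mitochondrial transcript levels stays open beside RNA quality and handling.

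The third pattern is the number of higher genes next to Foxo4, which might reflect a local effect of the mutated chromosome. Windows around 6135 other tested genes had at least as many tested neighbours. Of these, 4.25% held as large a share of higher genes as the 7 of 20 here. The direction was taken from these same neighbours and the windows overlap, so position by chance is not excluded. In either direction 8 of the 20 passed, against 44% of all tested genes. On unique reads 6 of the 7 were called higher, which argues against shared reads. Without Kif4a and Ercc6l in this window 21.1% of windows held as large a share, but the other windows kept their mitotic genes, so the share fell by construction and decides nothing. Whether chance, mitotic genes or a local effect account for the higher neighbours stays open.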
